A study of Saccharomyces cerevisiae with 15 samples.

How the data were processed

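Single-colour Affymetrix YG_S98 arrays of Saccharomyces cerevisiae CEN.PK113-7D were compared, 3 for each of 5 sole nitrogen sources, from aerobic glucose-limited chemostats. Per the labels, the medium held 7.5 g/l glucose, cultures ran for 10 to 14 volume changes with dissolved oxygen above 50%, and the molecule is polyA RNA. The deposited values are 1 linear signal intensity per probe set and array, made by the authors with MAS5 per the submitters' processing notes, and its version and scaling target are not given in the sources used here. The mean of each array without the top and bottom 2% of probe sets was nearly equal (150.09 to 150.15), so the deposited intensities had been scaled globally, which sets array means equal but not their distributions. The table held no detection flags, and 310 of its values were 0. Groups and array numbers come from the labels, and no array was left out. The labels state triplicates for each condition but not separate cultures, so p-values measure the spread between these samples, which may be technical.

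Of 9335 probe sets 60 controls were removed, leaving 9275. By the platform annotation 6504 of these name 1 gene, 328 several and 2443 none, and all 6504 matched the RefSeq gene table, which changed no symbol. Genes are named only from probe sets with 1 gene. Signals were floored at 1.9, the 10th percentile, and log2 transformed, and probe sets above the 25th percentile of their array on at least 3 of 15 arrays were tested, 7459 in all (80.4%). Of these 5928 name 1 gene (5388 genes), 1246 none, and 1238 carry the suffix of probe sets with shared sequence, whose values are uncertain. A gene with several probe sets was represented by the one with the highest mean. Of 271 genes with several tested probe sets 0 had calls in both directions with proline and with leucine, 2 with phenylalanine, 11 with methionine and 4 in the contrast of 3 sources with 2. Where the probe set used was called, another of the same gene was not for 23 of 29 genes with proline and 42 of 60 with leucine. The same held for 54 of 77 with phenylalanine, 68 of 107 with methionine and 51 of 82 in that contrast. Among genes named here, another probe set did not pass where the one used did for LEU2 with leucine, DAL5 with proline, and BDS1, PDR5 and COX1 with methionine. Folds are on the floored log2 scale, which understates changes of dim probe sets. Where the mean of a group was at or below 9.9, the 25th percentile of signal, the fold is given as at least the ratio to that bound.

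limma 3.58.1 in R 4.3.3 fitted 1 mean per group over all 15 arrays (lmFit, contrasts.fit, eBayes with trend), with 2-sided tests, Benjamini-Hochberg adjustment within each comparison and an adjusted p threshold of 0.05. The comparisons were the moderated F test over the 5 groups, each source against asparagine, leucine, phenylalanine and methionine against asparagine and proline, and probe sets specific to 1 source. The 4 comparisons with asparagine share its 3 arrays. Camera tested 35 gene lists written from general knowledge of yeast in each of 5 comparisons, with a preset correlation between genes of 0.01 and, as an alternative, an estimated one, and its p-values were adjusted over all 175 tests. The lists held 604 different genes, of which 553 were measured.

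The lists were nitrogen catabolite repression, allantoin and urea use, proline use, asparagine and aspartate metabolism, central nitrogen metabolism, the Ehrlich pathway, amino acid and peptide uptake, branched-chain amino acid synthesis, sulfur assimilation and methionine synthesis, sulfur source scavenging and sulfonates, aromatic amino acid synthesis and general amino acid control. They went on with multidrug and weak acid export, vacuolar proteases, the tricarboxylic acid and glyoxylate cycles, the retrograde response, oxidative phosphorylation, hexose transport, storage carbohydrate metabolism, glycolysis and ethanol formation, cytosolic ribosomal proteins, the general stress response, heat shock chaperones and thiamine synthesis. The rest were phosphate limitation, zinc limitation, iron limitation, copper uptake, ergosterol synthesis, fatty acid beta oxidation and the peroxisome, purine synthesis, MATa and MATalpha haploid identity, sporulation and meiosis, and flocculation and invasive growth. Some genes are on several lists.

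Named genes followed a rule: in each comparison the 10 largest changes each way among single-gene probe sets past the threshold whose arrays did not overlap between the groups (chance gives 10% for 3 against 3), key genes chosen per comparison, and up to 4 members of each list with the smallest adjusted p. For source-specific sets it took the 10 with the largest smallest difference each way. The comparisons, lists, key genes, this rule and most alternatives were fixed before the data were examined. The alternatives among them were quantile normalization, median centring, other floors and filters, no variance trend, array weights, the array number as a block, a 2-fold minimum, an adjusted p under 0.01, 1 probe set per gene, an estimated correlation, only the 2 groups compared, each array left out, and only the phenylalanine array with the usual code. Covariates from the actin ratio, the SPT15 ratio and the hybridisation controls, and leaving out 5 arrays with high ribosomal RNA signal, were chosen after seeing the data.

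The fits were tested on simulated data with 200 changed probe sets among 7459. Changes of 1.5-, 2- and 4-fold were recovered with the right sign for 29.2%, 61.4% and 90.8% of probe sets with proline, 27.4%, 72.3% and 91.8% with leucine, 23.9%, 67.6% and 91.5% with phenylalanine, 17.5%, 56.9% and 91.7% with methionine, and 63.0%, 86.4% and 93.4% in the contrast of 3 sources with 2. Of 7259 unchanged probe sets 5, 12, 8, 10 and 11 were called in the same order. For source-specific sets, 4-fold changes were recovered for 87.5% with asparagine, 91.5% with proline, 91.5% with leucine, 90.5% with phenylalanine and 90% with methionine, and 0 unchanged ones were called. A simulated change of the ergosterol synthesis list was called by camera, and 0 of the other 34 lists were. Simulated probe sets varied independently of each other, so this cannot test the preset correlation between genes.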

Results

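Messenger RNA levels were measured in the prototrophic haploid laboratory strain CEN.PK113-7D of Saccharomyces cerevisiae, of mating type a, grown in aerobic chemostats in which glucose limited growth and 1 amino acid was the sole nitrogen source. The 5 sources were asparagine (5.0 g/l), proline (8.8 g/l), leucine (10.0 g/l), phenylalanine (5.0 g/l) and methionine (11.3 g/l), with 3 arrays each, 15 in all. The title of the series sets preferred against non-preferred nitrogen sources, and asparagine, the source classed here as preferred, served as the reference for the other 4. The medium also held potassium sulfate (6.6 g/l), and cells were taken at a dilution rate of 0.10 per hour, 30 °C and pH 5.0. The median signal of an array ranged from 38.2 to 55.1 and the trimmed mean from 150.09 to 150.15. The number of arrays limits the precision. Signals of the 15 pairs of arrays within a group correlated at 0.950 to 0.982 across probe sets (median 0.973), against 0.868 to 0.962 (median 0.929) for the 90 pairs between groups, where probe sets are not independent replicates. No 2 arrays held identical values.

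Control probe sets were summarised by group. The ratio of the 3' to the 5' probe set of actin, a measure of RNA integrity and labelling length, was 2.77 ± 0.797 (SD, n = 3) with asparagine, 1.90 ± 0.427 with proline, 2.11 ± 0.285 with leucine, 2.81 ± 0.697 with phenylalanine and 1.76 ± 0.103 with methionine. The same ratio of SPT15, which encodes the TATA-binding protein, was 4.45 ± 0.264, 4.35 ± 0.763, 3.86 ± 0.741, 2.99 ± 1.10 and 3.57 ± 0.181 in the same order, lower with each of leucine, phenylalanine and methionine than with asparagine or proline. The signal of the hybridisation controls, transcripts added in fixed amounts, was 351 ± 58.2, 139 ± 28.2, 226 ± 106, 450 ± 319 and 173 ± 15.6 in the same order. The signal of the ribosomal RNA control probe sets was 18.0 ± 5.28, 57.0 ± 37.4, 55.2 ± 57.9, 28.2 ± 20.2 and 66.8 ± 90.6. Counts were also taken with each of the first 3 measures as a covariate and without the 5 arrays of high ribosomal RNA signal, alternatives that were chosen after seeing the data.

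Which transcripts depended on the nitrogen source was asked first. Of 7459 probe sets tested, 3892 (52.2%) differed among the 5 sources by limma's moderated F test, 1824 of them by at least 2-fold between 1 or more pairs of the 5 sources. The first principal component held 29.6% of the variance and the second 22.9%. Against asparagine, the most probe sets differed with methionine (2876, with 1070 higher and 1806 lower), followed by phenylalanine (1910, 563 higher and 1347 lower), leucine (1560, 737 and 823) and proline (992, 343 and 649). The order of phenylalanine and leucine turned with quantile normalization (1655 against 1764) and with a 2-fold minimum (587 against 599). The split between higher and lower calls moved with the scaling of the arrays. With quantile normalization and with median centring of each array it was 487 higher and 547 lower and then 449 and 442 with proline, 912 and 852 and then 801 and 750 with leucine, 844 and 811 and then 1112 and 607 with phenylalanine, and 1495 and 1564 and then 1520 and 1279 with methionine. The median log2 difference of all tested probe sets was -0.16 with phenylalanine and -0.09 with methionine as deposited, against 0.01 and 0.02 with quantile normalization and 0.08 and 0.06 with median centring, and changes are read relative to these shifts.

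**Figure D1:**
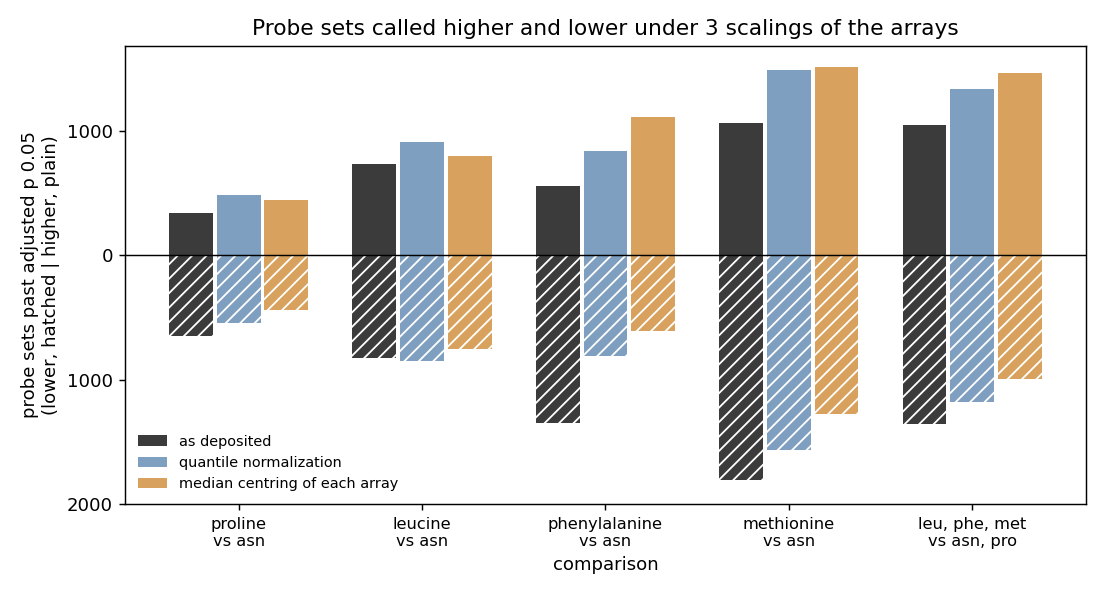
Number of probe sets higher and lower in each comparison (y axis) under the deposited scaling, quantile normalization and median centring (x axis groups), from 7459 tested probe sets on 15 arrays. With phenylalanine the lower calls outnumber the higher ones as deposited (1347 against 563), but the balance turns under quantile normalization (811 against 844) and median centring (607 against 1112).

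Proline was compared with asparagine to show the response to a source with catabolic enzymes of its own. Levels are the mean ± SD of 3 arrays, given from asparagine to the other source. PUT1 (YLR142W), the mitochondrial proline oxidase, was 16.0-fold higher (from 73.9 ± 16.6 to 1169 ± 144). PUT2, the enzyme of the next step to glutamate, was 3.19-fold higher (from 306 ± 26.8 to 974 ± 14.7). The ammonium permease MEP2 (YNL142W) rose 32.6-fold (from 36.6 ± 7.82 to 1174 ± 9.91), the general amino acid permease GAP1 10.8-fold (from 187 ± 34.2 to 1999.6 ± 174) and the GATA-family repressor DAL80 at least 14.9-fold (from 5.77 ± 6.22 to 161 ± 9.75). Several amino acid permeases were lower, BAP3 (branched-chain amino acids) by at least 30.0-fold (from 299 ± 43.9 to 4.87 ± 1.79), TAT1 (tyrosine, tryptophan and branched-chain amino acids) by at least 28.8-fold (from 289 ± 54.0 to 7.83 ± 0.850), MUP1 (methionine) by 10.7-fold (from 644 ± 19.8 to 60.8 ± 9.88) and GNP1 (glutamine) by 7.87-fold (from 527 ± 43.6 to 67.0 ± 6.30). The proline permease PUT4 was 1.57-fold higher (from 1001 ± 113 to 1572 ± 189, adjusted p = 0.0066), with a log2 difference of 0.65 ± 0.14 (SE). The PUT4 call was lost with the actin ratio as covariate (0.41 ± 0.12, adjusted p = 0.070). It was also lost, with a larger SE, with the hybridisation control signal as covariate (0.60 ± 0.18, adjusted p = 0.060) and without the arrays of high ribosomal RNA signal (0.73 ± 0.21, adjusted p = 0.10), which leaves 1 proline array. The activator PUT3 (from 127 ± 17.1 to 125 ± 22.2, adjusted p = 0.92) and the cytosolic asparaginase ASP1 (from 266 ± 88.9 to 325 ± 8.45, 0.28) did not pass.

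Nitrogen catabolite repression keeps genes for poor nitrogen sources low on rich ones, and of its 38 measured genes 29 rose and 3 fell (30 and 3 adjusted over the list alone, median log2 difference 1.31, adjusted p = 1.3e-33) with proline. Adjusted p-values of lists are those of camera, which compares a list with all other genes. Of 9 genes of allantoin and urea use, 7 rose and 0 fell (the same adjusted over the list alone, median log2 difference 2.77, adjusted p = 1.6e-16). They included the ureidoglycolate lyase DAL3, 11.2-fold higher (from 116 ± 8.55 to 1291 ± 64.9), the allantoate permease DAL5 (7.50-fold) and the urea transporter DUR3 (6.84-fold). All 5 genes of central nitrogen metabolism passed: 5 rose and 0 fell (the same adjusted over the list alone, median log2 difference 1.19, adjusted p = 8.8e-11), with glutamine synthetase GLN1 3.50-fold and the glutamate dehydrogenase GDH3 4.93-fold higher. Of 7 proline use genes, 3 rose and 0 fell (4 and 1 adjusted over the list alone, median log2 difference 0.32, adjusted p = 6.2e-04, and adjusted p = 0.10 with an estimated correlation). Of 26 amino acid and peptide uptake genes, 4 rose and 9 fell (4 and 10 adjusted over the list alone, median log2 difference -0.21, adjusted p = 7.8e-04, and adjusted p = 0.26 with an estimated correlation). General amino acid control, the biosynthetic regulon of GCN4, had 32 measured genes, of which 12 rose and 0 fell (19 and 0 adjusted over the list alone, median log2 difference 0.44, adjusted p = 1.3e-08). Of 10 vacuolar proteases, 3 rose and 0 fell (5 and 0 adjusted over the list alone, median log2 difference 0.39, adjusted p = 5.8e-04), with the endoprotease PRB1 1.73-fold higher.

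Outside nitrogen metabolism, iron limitation genes were lower with proline: of 24, 0 rose and 7 fell (0 and 13 adjusted over the list alone, median log2 difference -0.45, adjusted p = 5.7e-06, and adjusted p = 0.12 with an estimated correlation). The siderophore transporters SIT1 and ENB1 were 4.28-fold lower (from 412 ± 152 to 91.9 ± 0.416) and 1.80-fold lower (from 376 ± 59.0 to 207 ± 20.9). Of 25 ergosterol synthesis genes, 10 rose and 0 fell (13 and 2 adjusted over the list alone, median log2 difference 0.34, adjusted p = 3.8e-05, and adjusted p = 0.072 with an estimated correlation). Of 16 purine synthesis genes, 3 rose and 0 fell (5 and 0 adjusted over the list alone, median log2 difference 0.25, adjusted p = 2.9e-04, and adjusted p = 0.16 with an estimated correlation), with the glycine decarboxylase subunit GCV2 1.85-fold higher. Of 24 general stress genes, 5 rose and 0 fell (the same adjusted over the list alone, median log2 difference 0.09, adjusted p = 0.019, and adjusted p = 0.26 with an estimated correlation), with the cell wall protein SPI1 2.02-fold and the peroxiredoxin TSA2 2.53-fold higher. The stress call was lost with a filter at the 50th percentile (adjusted p = 0.075), with array weights (adjusted p = 0.056), without asparagine 2 (adjusted p = 0.10), without proline 3 (adjusted p = 0.064) and without the arrays of high ribosomal RNA signal (adjusted p = 0.16). Of 28 genes of the tricarboxylic acid and glyoxylate cycles, 8 rose and 1 fell (10 and 2 adjusted over the list alone, median log2 difference 0.16, adjusted p = 0.013, and adjusted p = 0.17 with an estimated correlation). The cycle call was lost with quantile normalization (median 0.14, adjusted p = 0.17), under which the median of all tested probe sets moved from -0.08 to 0.01. Of 34 oxidative phosphorylation genes, 4 rose and 0 fell (7 and 0 adjusted over the list alone, median log2 difference 0.10, adjusted p = 0.013, and adjusted p = 0.31 with an estimated correlation). The oxidative phosphorylation call was lost with quantile normalization (median 0.11, adjusted p = 0.14) and, at a smaller median, without asparagine 2 (median 0.039, adjusted p = 0.12). The actin ratio (1.90 against 2.77) and the hybridisation control signal (139 against 351) were lower with proline than with asparagine. The count of 992 was 330 with the first and 476 with the second as covariate, 2095 with array weights, and 173 without the arrays of high ribosomal RNA signal, which leaves 1 proline array. It was 527 without asparagine 1, 366 without asparagine 3, 409 without proline 1 and 500 without proline 2.

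**Figure D2:**
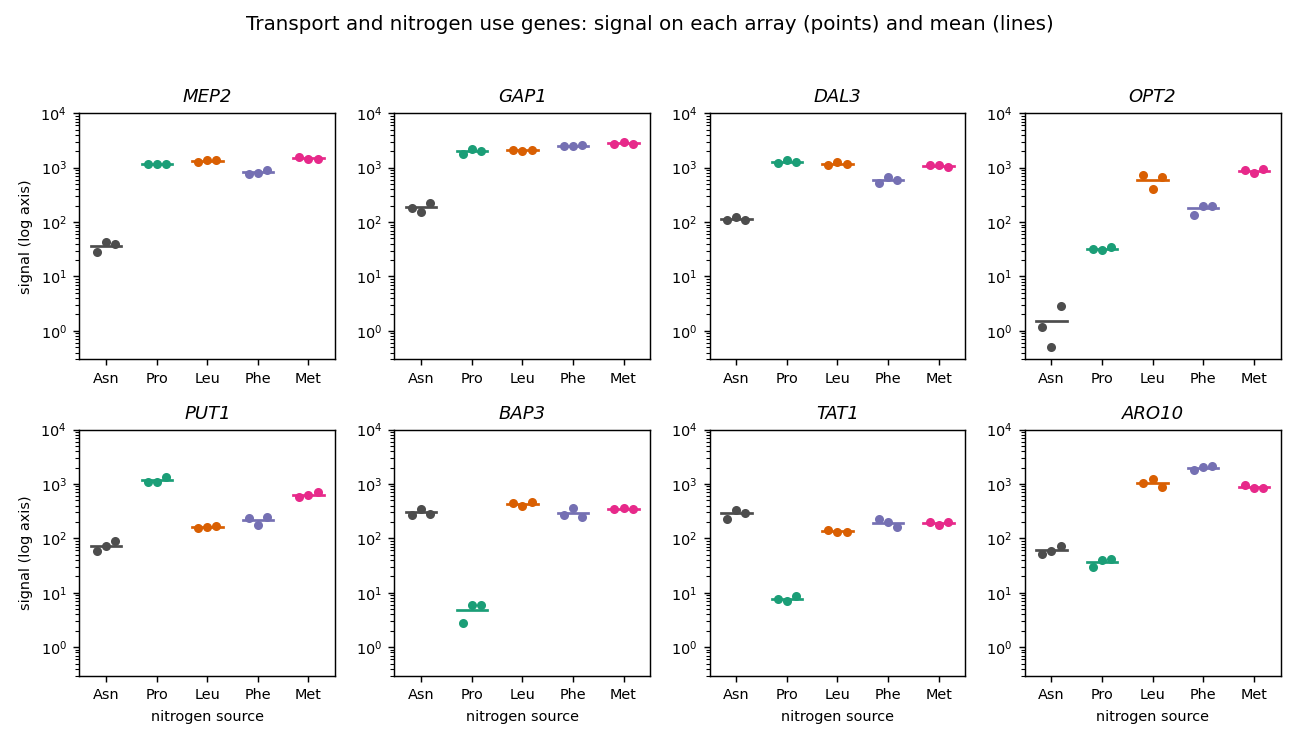
Deposited signal (y axis, log scale) of MEP2, GAP1, DAL3, OPT2, PUT1, BAP3, TAT1 and ARO10 on each of the 15 arrays, as points by nitrogen source (x axis), with the mean of each group. MEP2 averages 36.6 with asparagine and between 823 and 1495 with the other 4 sources, and BAP3 averages 4.87 with proline and at least 290.5 with each other source.

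Leucine use begins with a transamination that leaves a branched-chain keto acid. Against asparagine, the cytosolic branched-chain aminotransferase BAT2 rose 5.49-fold (from 245 ± 44.6 to 1329.8 ± 95.5) and the keto acid decarboxylase ARO10 17.2-fold (from 60.9 ± 10.6 to 1046 ± 168). The mitochondrial aminotransferase BAT1 was 1.45-fold lower (from 422 ± 23.3 to 290.5 ± 15). Within leucine synthesis, isopropylmalate isomerase LEU1 (YGL009C) was 4.08-fold lower (from 579 ± 73.4 to 142 ± 13.6). Isopropylmalate dehydrogenase LEU2 was 2.54-fold lower (from 1422 ± 72.7 to 560.1 ± 48.9). OAC1, a mitochondrial carrier of oxaloacetate and isopropylmalate, was 2.20-fold lower (from 655 ± 87.9 to 298 ± 43.9). The isopropylmalate synthase LEU9 was 2.13-fold higher (from 76.5 ± 5.81 to 163 ± 13.9). LEU4, the other one, was 1.55-fold higher (from 1336 ± 206 to 2064 ± 281, adjusted p = 0.016), a call lost without asparagine 1 (0.085) or leucine 2 (0.070). The permeases BAP2 (from 632 ± 137 to 630.3 ± 46.7, adjusted p = 0.95) and BAP3 (from 299 ± 43.9 to 437 ± 38.9, 0.12) and the decarboxylase PDC5 (from 64.1 ± 6.40 to 73.4 ± 7.32, 0.55) did not pass. Of 12 branched-chain amino acid synthesis genes, 6 rose and 4 fell (the same adjusted over the list alone, median log2 difference 0.35, adjusted p = 0.65), so the list was not called.

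With leucine, the oligopeptide transporter OPT2 was at least 58.5-fold higher (from 1.53 ± 1.23 to 597 ± 169). The peptide transporter PTR2 was 27.6-fold higher (from 32.1 ± 3.60 to 888 ± 122). The weak acid exporter PDR12 was 23.6-fold higher (from 79.6 ± 44.3 to 1657 ± 37.1). Of 38 nitrogen catabolite repression genes, 28 rose and 1 fell (31 and 1 adjusted over the list alone, median log2 difference 1.46, adjusted p = 8.4e-22), among them the ammonium permease MEP3 (12.3-fold). Of 9 allantoin and urea genes, 8 rose and 0 fell (the same adjusted over the list alone, median log2 difference 1.54, adjusted p = 1.3e-09). Of 5 of central nitrogen metabolism, 4 rose and 0 fell (5 and 0 adjusted over the list alone, median log2 difference 1.09, adjusted p = 7.3e-06), with GDH3 10.9-fold higher. Of 32 genes of general amino acid control, 27 rose and 0 fell (28 and 0 adjusted over the list alone, median log2 difference 1.09, adjusted p = 9.4e-18), including the vitamin B6 genes SNO1 (7.82-fold) and SNZ1 (5.96-fold), ornithine carbamoyltransferase ARG3 (3.59-fold) and HIS3 of histidine synthesis (3.08-fold). Of 12 aromatic amino acid synthesis genes, 9 rose and 0 fell (the same adjusted over the list alone, median log2 difference 0.83, adjusted p = 2.2e-07), with TRP3 of tryptophan synthesis 3.11-fold higher. Of 33 genes of sulfur assimilation and methionine synthesis, 14 rose and 2 fell (15 and 2 adjusted over the list alone, median log2 difference 0.37, adjusted p = 0.0011, and adjusted p = 0.16 with an estimated correlation). Of 5 genes of asparagine and aspartate metabolism, 4 rose and 0 fell (the same adjusted over the list alone, median log2 difference 0.64, adjusted p = 0.0058, and adjusted p = 0.17 with an estimated correlation). Of 16 of purine synthesis, 7 rose and 0 fell (the same adjusted over the list alone, median log2 difference 0.38, adjusted p = 6.7e-04, and adjusted p = 0.18 with an estimated correlation). Of 7 proline use genes, 2 rose and 0 fell (3 and 0 adjusted over the list alone, median log2 difference 0.31, adjusted p = 0.030, and adjusted p = 0.26 with an estimated correlation). The proline use call was lost with quantile normalization (median 0.28, adjusted p = 0.067).

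The retrograde response links mitochondrial function to glutamate supply, and of its 11 genes 7 rose and 0 fell (the same adjusted over the list alone, median log2 difference 0.82, adjusted p = 3.7e-06) with leucine. Peroxisomal citrate synthase CIT2 was 5.04-fold higher (from 237 ± 35.1 to 1186 ± 112) and isocitrate dehydrogenase IDH1 2.90-fold higher. Of 28 genes of the tricarboxylic acid and glyoxylate cycles, 13 rose and 5 fell (14 and 6 adjusted over the list alone, median log2 difference 0.37, adjusted p = 0.011, and adjusted p = 0.16 with an estimated correlation). Of 34 oxidative phosphorylation genes, 9 rose and 2 fell (11 and 2 adjusted over the list alone, median log2 difference 0.20, adjusted p = 0.013, and adjusted p = 0.31 with an estimated correlation). The oxidative phosphorylation call was lost without asparagine 2 (adjusted p = 0.070) and without leucine 2 (adjusted p = 0.074). Of 24 iron limitation genes, 11 rose and 1 fell (14 and 1 adjusted over the list alone, median log2 difference 0.49, adjusted p = 3.6e-04, and adjusted p = 0.22 with an estimated correlation). The siderophore wall protein FIT2 was 6.33-fold higher (from 296 ± 196 to 1636 ± 33.9).

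Stress genes fell with leucine. The hydrophilin GRE1 (YPL223C) was 85.2-fold lower (from 1797 ± 360 to 20.9 ± 2.52). The cell wall mannoprotein HPF1 was 57.1-fold lower (from 1880 ± 483 to 34.9 ± 15.4). The secreted glycoprotein YGP1 was 15.6-fold lower (from 1572 ± 86.5 to 101 ± 4.76). The membrane-associated HSP12 was 7.16-fold lower (from 3761 ± 546 to 528 ± 93.4). Of 24 general stress genes, 1 rose and 19 fell (1 and 20 adjusted over the list alone, median log2 difference -1.86, adjusted p = 3.1e-18). Of 19 heat shock chaperones, 0 rose and 11 fell (1 and 12 adjusted over the list alone, median log2 difference -0.58, adjusted p = 8.8e-06), with the Hsp70 gene SSA3 17.2-fold lower. Of 16 genes of storage carbohydrate metabolism, 1 rose and 10 fell (the same adjusted over the list alone, median log2 difference -0.68, adjusted p = 6.8e-04, and adjusted p = 0.26 with an estimated correlation), including phosphoglucomutase PGM2 (3.24-fold) and trehalose phosphatase TPS2 (2.56-fold). Of 18 genes of glycolysis and ethanol formation, 0 rose and 7 fell (1 and 9 adjusted over the list alone, median log2 difference -0.36, adjusted p = 0.0036, and adjusted p = 0.072 with an estimated correlation). Of 25 of ergosterol synthesis, 2 rose and 12 fell (4 and 16 adjusted over the list alone, median log2 difference -0.45, adjusted p = 4.8e-04, and adjusted p = 0.12 with an estimated correlation), with squalene epoxidase ERG1 2.17-fold lower. The actin ratio was 2.11 and the hybridisation control signal 226, against 2.77 and 351 with asparagine. No array left out on its own moved the count of 1560 by over 1.5 times.

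Phenylalanine yields an aromatic keto acid on transamination. Against asparagine, ARO10 (YDR380W), which decarboxylates it, was 33.0-fold higher (from 60.9 ± 10.6 to 1996 ± 202). The aromatic aminotransferase ARO9 was 5.81-fold higher (from 316 ± 25.6 to 1837 ± 192). Their activator ARO80 was 2.71-fold higher (from 15.3 ± 1.12 to 41.8 ± 7.45). The putative monocarboxylate permease ESBP6 was 2.60-fold higher (from 305 ± 33.5 to 797 ± 143). PDR12 rose 27.3-fold (from 79.6 ± 44.3 to 1933 ± 265), OPT2 at least 17.7-fold (from 1.53 ± 1.23 to 178 ± 38.1) and GAP1 13.8-fold (from 187 ± 34.2 to 2550.2 ± 79.1). The aminotransferase ARO8 was 1.34-fold higher (from 557 ± 84.8 to 743 ± 92.0, adjusted p = 0.018). The permease TAT1 was 1.49-fold lower (from 289 ± 54.0 to 194 ± 31.2, 0.017). ARO3, the first enzyme of aromatic synthesis, was 1.32-fold lower (from 129.6 ± 16.2 to 98.6 ± 13.2, 0.042). The log2 difference of ARO8 was 0.42 ± 0.12 (SE), and its call was lost without asparagine 1 (0.39 ± 0.14, adjusted p = 0.054), asparagine 3 (0.33 ± 0.13, 0.093) or phenylalanine 2 (0.32 ± 0.12, 0.053). It was also lost, at no smaller a difference but a larger SE, with only the 2 groups fitted (0.42 ± 0.17, 0.14) and without the arrays of high ribosomal RNA signal (0.47 ± 0.15, 0.076). For TAT1 (-0.57 ± 0.16) the call was lost at a smaller difference without asparagine 2 (-0.45 ± 0.17, 0.083) or phenylalanine 3 (-0.44 ± 0.16, 0.076), with median centring (-0.33 ± 0.14, 0.11) and without the arrays of high ribosomal RNA signal (-0.44 ± 0.18, 0.13). It was lost at a similar difference and a larger SE without asparagine 3 (-0.55 ± 0.19, 0.061), with phenylalanine 2 as the only array of its group (-0.53 ± 0.21, 0.11), with the SPT15 ratio as covariate (-0.58 ± 0.22, 0.098) and with only the 2 groups fitted (-0.57 ± 0.20, 0.098). For ARO3 (-0.40 ± 0.13) the call was lost at a difference smaller by over 1 SE with quantile normalization (-0.19 ± 0.13, 0.33), median centring (-0.15 ± 0.13, 0.45), phenylalanine 2 as the only array of its group (-0.18 ± 0.17, 0.54) or the SPT15 ratio as covariate (-0.20 ± 0.16, 0.47). It was also lost without asparagine 1 (-0.37 ± 0.15, 0.10), asparagine 3 (-0.32 ± 0.15, 0.16), phenylalanine 1 (-0.34 ± 0.15, 0.12), phenylalanine 3 (-0.34 ± 0.14, 0.12) or the arrays of high ribosomal RNA signal (-0.34 ± 0.17, 0.21), with only the 2 groups fitted (-0.40 ± 0.18, 0.19), and, at the same difference, without proline 1, leucine 1, leucine 3 or any methionine array (0.053 to 0.055). PDC5 (from 64.1 ± 6.40 to 86.9 ± 32.1, 0.18) and prephenate dehydratase PHA2 (from 40.4 ± 2.96 to 45.5 ± 1.68, 0.38) did not pass.

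Of 38 nitrogen catabolite repression genes, 25 rose and 2 fell (27 and 2 adjusted over the list alone, median log2 difference 0.93, adjusted p = 2.4e-21) with phenylalanine. Of 9 allantoin and urea genes, 7 rose and 0 fell (8 and 0 adjusted over the list alone, median log2 difference 0.95, adjusted p = 3.4e-08). Of 5 of central nitrogen metabolism, 3 rose and 0 fell (5 and 0 adjusted over the list alone, median log2 difference 1.08, adjusted p = 6.0e-07). Of 12 aromatic amino acid synthesis genes, 2 rose and 3 fell (3 and 3 adjusted over the list alone, median log2 difference 0.10, adjusted p = 0.38), a list not called, whose median and mean differ in sign. Of 12 branched-chain amino acid synthesis genes, 6 rose and 0 fell (7 and 0 adjusted over the list alone, median log2 difference 0.37, adjusted p = 1.6e-05). Respiratory genes were higher: of 34 in oxidative phosphorylation, 24 rose and 2 fell (25 and 2 adjusted over the list alone, median log2 difference 0.49, adjusted p = 8.4e-13). Cytochrome c CYC1 was 1.89-fold higher (from 1049 ± 11.3 to 1984 ± 137), as were the cytochrome oxidase subunits COX9 (1.75-fold) and COX4 (1.65-fold). Of 28 genes of the tricarboxylic acid and glyoxylate cycles, 17 rose and 5 fell (20 and 5 adjusted over the list alone, median log2 difference 0.60, adjusted p = 1.1e-09). Of 11 of the retrograde response, 6 rose and 0 fell (the same adjusted over the list alone, median log2 difference 0.74, adjusted p = 7.8e-07). CIT2 was 6.10-fold higher (from 237 ± 35.1 to 1458 ± 325). Of 24 iron limitation genes, 8 rose and 1 fell (the same adjusted over the list alone, median log2 difference 0.27, adjusted p = 1.7e-04, and adjusted p = 0.19 with an estimated correlation). FIT2 was 7.41-fold higher (from 296 ± 196 to 1919 ± 153). Of 32 genes of general amino acid control, 10 rose and 4 fell (14 and 4 adjusted over the list alone, median log2 difference 0.27, adjusted p = 0.0010, and adjusted p = 0.21 with an estimated correlation). Of 6 of MATa identity, 2 rose and 0 fell (the same adjusted over the list alone, median log2 difference 0.35, adjusted p = 0.011, and adjusted p = 0.064 with an estimated correlation). Of 30 cytosolic ribosomal protein genes, 4 rose and 0 fell (the same adjusted over the list alone, median log2 difference 0.26, adjusted p = 2.2e-04, and adjusted p = 0.36 with an estimated correlation). The ribosomal protein call was lost with quantile normalization (adjusted p = 0.63). Of 7 proline use genes, 2 rose and 1 fell (5 and 2 adjusted over the list alone, median log2 difference 0.27, adjusted p = 0.022, and adjusted p = 0.25 with an estimated correlation). The proline use call was lost with quantile normalization (median 0.27, adjusted p = 0.13), under which the median of all tested probe sets moved from -0.16 to 0.01. It was also lost without phenylalanine 1 (median 0.19, adjusted p = 0.065). Of 16 purine synthesis genes, 5 rose and 0 fell (the same adjusted over the list alone, median log2 difference 0.06, adjusted p = 0.032, and adjusted p = 0.35 with an estimated correlation). The purine call was lost with quantile normalization (adjusted p = 0.38), without asparagine 1 (adjusted p = 0.067), without asparagine 3 (adjusted p = 0.056), without phenylalanine 1 (adjusted p = 0.064), without phenylalanine 3 (adjusted p = 0.097), with phenylalanine 2 as the only array of its group (adjusted p = 0.47), with the SPT15 ratio as covariate (adjusted p = 0.13) and without the arrays of high ribosomal RNA signal (adjusted p = 0.11). In the fit with phenylalanine 2 alone the purine median turned to -0.03.

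Among lower genes with phenylalanine, GRE1 was 75.2-fold lower (from 1797 ± 360 to 23.8 ± 4.28). HPF1 was 37.9-fold lower (from 1880 ± 483 to 50.0 ± 14.2). The hexose transporter HXT5 was 17.4-fold lower (from 931 ± 105 to 61.9 ± 34.2). The plasma membrane ATPase isoform PMA2 was 12.4-fold lower (from 478 ± 109.5 to 38.5 ± 7.26). Of 24 general stress genes, 1 rose and 16 fell (2 and 16 adjusted over the list alone, median log2 difference -0.92, adjusted p = 6.3e-06, and adjusted p = 0.054 with an estimated correlation). Of 19 heat shock chaperones, 1 rose and 12 fell (2 and 13 adjusted over the list alone, median log2 difference -0.66, adjusted p = 2.6e-04, and adjusted p = 0.092 with an estimated correlation), with the Hsp90 cochaperone STI1 1.92-fold lower. Of 25 ergosterol synthesis genes, 1 rose and 17 fell (1 and 18 adjusted over the list alone, median log2 difference -0.63, adjusted p = 1.6e-05, and adjusted p = 0.062 with an estimated correlation), with the methyl sterol oxidase ERG25 2.09-fold lower. Per the labels, phenylalanine 2 alone has an array code of the form used in the other groups, and per the file headers phenylalanine 1 is a repeat run after scanner servicing. The SPT15 ratio was 2.99, against 4.45 with asparagine, and with it as covariate the count of 1910 was 822 (279 higher and 543 lower). With phenylalanine 2 as the only array of its group, assumed to vary like the others, the count of 1910 was 921, of which 37.6% were higher. It was 1174 without asparagine 3, 840 with only the 2 groups fitted and 895 without the arrays of high ribosomal RNA signal.

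Methionine supplies sulfur as well as nitrogen, and sulfate assimilation genes were lower than with asparagine. The sulfate permease SUL1 was 9.91-fold lower (from 658 ± 76.5 to 66.7 ± 11.1). ATP sulfurylase MET3 (YJR010W) was 9.84-fold lower (from 703 ± 97.1 to 71.7 ± 11.8). Adenylylsulfate kinase MET14 was 9.75-fold lower (from 1088 ± 89.3 to 111 ± 7.62). Phosphoadenylylsulfate reductase MET16 was 3.85-fold lower (from 217 ± 61.5 to 55.0 ± 3.11). Homocysteine synthase MET17 was 4.35-fold lower (from 3198 ± 257 to 734 ± 18.4). Methionine synthase MET6 was 4.09-fold lower (from 763 ± 124 to 185 ± 13.7). The homoserine acetyltransferase MET2 was at least 35.6-fold lower (from 352 ± 6.76 to 3.30 ± 1.56). The regulator MET32 was at least 22.2-fold lower (from 219.7 ± 8.58 to 8.00 ± 1.35). The S-methylmethionine methyltransferase MHT1 was at least 15-fold lower (from 149 ± 21.1 to 2.93 ± 1.87). The S-methylmethionine permease MMP1 was 21.9-fold lower (from 478 ± 51.5 to 22.1 ± 4.07). The methionine permeases MUP1 (4.24-fold) and MUP3 (2.15-fold), the S-adenosylmethionine synthetases SAM1 (2.28-fold) and SAM2 (2.29-fold) and the pyruvate decarboxylase PDC6 (2.84-fold) were lower too. Of 33 genes of sulfur assimilation and methionine synthesis, 4 rose and 24 fell (the same adjusted over the list alone, median log2 difference -1.44, adjusted p = 1.2e-11).

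With methionine, OPT2 was at least 88.1-fold higher (from 1.53 ± 1.23 to 874 ± 77.8). PTR2 was 51.3-fold higher (from 32.1 ± 3.60 to 1652 ± 254). ARO10 was 14.8-fold higher (from 60.9 ± 10.6 to 896 ± 71.2). BAT2 was 6.26-fold higher (from 245 ± 44.6 to 1516 ± 42.5). ARO9 was 2.59-fold higher (from 316 ± 25.6 to 818 ± 37.1). The cysteine beta-lyase IRC7 was 18.4-fold higher (from 15.4 ± 2.70 to 281 ± 18.4). The low-affinity glucose transporter HXT3 was 11.3-fold higher (from 74.7 ± 16.5 to 831 ± 67.4). In the list of amino acid and peptide uptake 9 rose and 8 fell of 26 (the same adjusted over the list alone), and in that of the Ehrlich pathway 9 rose and 12 fell of 31 (12 and 12 adjusted over the list alone), and neither list was called (adjusted p = 0.14 and 0.16). Of 38 nitrogen catabolite repression genes, 34 rose and 1 fell (35 and 2 adjusted over the list alone, median log2 difference 2.05, adjusted p = 7.2e-29). Of 9 allantoin and urea genes, 7 rose and 0 fell (the same adjusted over the list alone, median log2 difference 2.63, adjusted p = 4.5e-09). Of 5 of central nitrogen metabolism, 5 rose and 0 fell (the same adjusted over the list alone, median log2 difference 1.16, adjusted p = 8.3e-07). Of 12 branched-chain amino acid synthesis genes, 11 rose and 0 fell (the same adjusted over the list alone, median log2 difference 0.69, adjusted p = 1.4e-06). Of 12 of aromatic amino acid synthesis, 8 rose and 0 fell (10 and 0 adjusted over the list alone, median log2 difference 0.56, adjusted p = 1.5e-04). Of 32 genes of general amino acid control, 20 rose and 1 fell (the same adjusted over the list alone, median log2 difference 0.75, adjusted p = 2.9e-08). Of 11 retrograde response genes, 7 rose and 1 fell (9 and 1 adjusted over the list alone, median log2 difference 1.29, adjusted p = 2.2e-05). Of 28 of the tricarboxylic acid and glyoxylate cycles, 18 rose and 5 fell (19 and 5 adjusted over the list alone, median log2 difference 0.52, adjusted p = 1.5e-04). Of 34 oxidative phosphorylation genes, 15 rose and 2 fell (16 and 2 adjusted over the list alone, median log2 difference 0.27, adjusted p = 1.6e-04, and adjusted p = 0.16 with an estimated correlation). Of 7 proline use genes, 4 rose and 0 fell (the same adjusted over the list alone, median log2 difference 0.41, adjusted p = 0.016, and adjusted p = 0.23 with an estimated correlation). PUT1 was 8.79-fold higher (from 73.9 ± 16.6 to 641 ± 63.6). The proline use call was lost with quantile normalization (median 0.33, adjusted p = 0.072). Of 16 purine synthesis genes, 4 rose and 0 fell (the same adjusted over the list alone, median log2 difference 0.27, adjusted p = 0.027, and adjusted p = 0.34 with an estimated correlation). The purine call was lost with quantile normalization (adjusted p = 0.20), without methionine 2 (adjusted p = 0.053), with the SPT15 ratio as covariate (adjusted p = 0.056) and without the arrays of high ribosomal RNA signal (adjusted p = 0.053).

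Of 6 genes of MATa identity, 5 rose and 0 fell (6 and 0 adjusted over the list alone, median log2 difference 1.42, adjusted p = 1.0e-04) with methionine. The protease BAR1, which degrades alpha-factor, was 3.48-fold higher (from 141 ± 26.6 to 487 ± 17.5). The a-factor exporter STE6 was 3.07-fold higher (from 60.3 ± 10.5 to 183 ± 3.95). The alpha-factor receptor STE2 was 2.91-fold higher (from 101 ± 10.8 to 292 ± 25.4). The a-factor gene MFA2 was 2.45-fold higher (from 814 ± 364 to 1887 ± 238). GRE1 was 109.6-fold lower (from 1797 ± 360 to 16.3 ± 2.06). HPF1 was 95.7-fold lower (from 1880 ± 483 to 19.6 ± 4.96). The copper transporter CTR3 was 23.0-fold lower (from 895 ± 256 to 37.6 ± 1.02). The acetate transporter ADY2 was 22.8-fold lower (from 919 ± 119 to 40.3 ± 5.73). Of 19 genes of fatty acid beta oxidation and the peroxisome, 2 rose and 13 fell (the same adjusted over the list alone, median log2 difference -0.73, adjusted p = 3.1e-04). The thiolase POT1 was 9.70-fold lower (from 1445 ± 108 to 149 ± 12.5) and the multifunctional enzyme FOX2 3.17-fold lower. Of 25 ergosterol synthesis genes, 1 rose and 14 fell (1 and 17 adjusted over the list alone, median log2 difference -0.49, adjusted p = 1.1e-04, and adjusted p = 0.088 with an estimated correlation), with the sterol methyltransferase ERG6 2.65-fold lower. Of 24 general stress genes, 3 rose and 14 fell (3 and 16 adjusted over the list alone, median log2 difference -0.66, adjusted p = 8.3e-04, and adjusted p = 0.15 with an estimated correlation). The actin ratio (1.76 against 2.77) and the hybridisation control signal (173 against 351) were lower with methionine than with asparagine, as was the SPT15 ratio (3.57 against 4.45). The count of 2876 was 1854 with the actin ratio as covariate, and no array left out on its own moved it by over 1.5 times.

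Leucine, phenylalanine and methionine are known to be used by transamination and to leave their carbon skeletons through the Ehrlich pathway, while carbon from asparagine and proline enters central metabolism, and the 3 were set against the 2. Of 7459 probe sets 2404 differed, 1052 higher and 1352 lower, and 445 of them by at least 2-fold (146 higher and 299 lower). This contrast takes the mean of the 3 group means minus that of the 2, so a gene that differs in only 1 source can pass. Of the Ehrlich pathway, ARO10 was 26.0-fold higher (log2 difference 4.70 ± 0.11 SE). PDR12 was 9.98-fold higher (log2 difference 3.32 ± 0.21 SE). ARO9 was 5.12-fold higher (log2 difference 2.36 ± 0.08 SE). BAT2 was 3.40-fold higher (log2 difference 1.77 ± 0.09 SE). The alcohol dehydrogenase ADH5 was 3.22-fold higher (log2 difference 1.69 ± 0.10 SE). ARO80 was 1.69-fold higher (log2 difference 0.76 ± 0.14 SE, adjusted p = 6.8e-04). Its signal averaged 41.8 with phenylalanine but 17.2 with leucine and 15.5 with methionine, against 15.3 with asparagine and 11.2 with proline. The ARO80 call was lost without the arrays of high ribosomal RNA signal (0.71 ± 0.22 SE), which leaves 1 proline array. PDC6 was 2.58-fold lower (log2 difference -1.37 ± 0.15 SE) and the alcohol and formaldehyde dehydrogenase SFA1 1.99-fold lower, while PDC5 (log2 difference 0.20 ± 0.13 SE, adjusted p = 0.28) and the decarboxylase homologue THI3 (0.21 ± 0.16 SE, 0.35) did not pass. Of 31 Ehrlich pathway genes, 10 rose and 10 fell (12 and 10 adjusted over the list alone, median log2 difference 0.12, adjusted p = 0.16), so the list went both ways and was not called.

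In the 3 sources the peptide transporter PTR2 was 27.0-fold higher (log2 difference 4.75 ± 0.17 SE). OPT2, whose mean with asparagine was below 9.9, was higher too (log2 difference of at least 4.64). The amino acid permease AGP1 was 6.91-fold higher (log2 difference 2.79 ± 0.10 SE). Of 26 amino acid and peptide uptake genes, 15 rose and 4 fell (16 and 7 adjusted over the list alone, median log2 difference 0.44, adjusted p = 6.3e-05, and adjusted p = 0.20 with an estimated correlation). Against asparagine the uptake list was called only with proline (median log2 difference -0.21). Of 38 nitrogen catabolite repression genes, 23 rose and 3 fell (23 and 4 adjusted over the list alone, median log2 difference 0.87, adjusted p = 7.8e-13). Of 9 of allantoin and urea use, 6 rose and 1 fell (the same adjusted over the list alone, median log2 difference 0.56, adjusted p = 2.1e-04). Of 5 central nitrogen metabolism genes, 3 rose and 0 fell (the same adjusted over the list alone, median log2 difference 0.59, adjusted p = 2.6e-04, and adjusted p = 0.083 with an estimated correlation). Of 32 genes of general amino acid control, 19 rose and 2 fell (21 and 2 adjusted over the list alone, median log2 difference 0.42, adjusted p = 4.4e-08). Of 12 of aromatic synthesis, 9 rose and 0 fell (the same adjusted over the list alone, median log2 difference 0.40, adjusted p = 9.8e-05). Of 12 of branched-chain synthesis, 7 rose and 1 fell (the same adjusted over the list alone, median log2 difference 0.37, adjusted p = 0.0043, and adjusted p = 0.17 with an estimated correlation). Of 11 retrograde response genes, 7 rose and 0 fell (the same adjusted over the list alone, median log2 difference 0.64, adjusted p = 1.3e-06). Of 28 of the tricarboxylic acid and glyoxylate cycles, 19 rose and 5 fell (20 and 5 adjusted over the list alone, median log2 difference 0.43, adjusted p = 2.0e-05). Of 34 oxidative phosphorylation genes, 22 rose and 2 fell (26 and 2 adjusted over the list alone, median log2 difference 0.31, adjusted p = 8.2e-07, and adjusted p = 0.068 with an estimated correlation). Of 24 iron limitation genes, 13 rose and 1 fell (the same adjusted over the list alone, median log2 difference 0.35, adjusted p = 3.1e-06, and adjusted p = 0.11 with an estimated correlation). FIT2 was 9.78-fold higher (log2 difference 3.29 ± 0.20 SE). Of 6 of MATa identity, 4 rose and 0 fell (5 and 0 adjusted over the list alone, median log2 difference 0.80, adjusted p = 3.9e-04). Of 5 asparagine and aspartate genes, 4 rose and 1 fell (the same adjusted over the list alone, median log2 difference 0.56, adjusted p = 0.035, and adjusted p = 0.26 with an estimated correlation). The asparagine and aspartate call was lost with quantile normalization (median 0.54, adjusted p = 0.065), with median centring (0.66, 0.067), without leucine 2 (0.54, 0.053) and without phenylalanine 3 (0.57, 0.053). It was also lost with the SPT15 ratio as covariate (0.41, 0.060) and, at a median of 0.43, with phenylalanine 2 as the only array of its group.

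Stress and sterol genes were lower in these 3 sources. GRE1 was 90.4-fold lower (log2 difference -6.50 ± 0.12 SE). HPF1 was 35.2-fold lower (log2 difference -5.14 ± 0.20 SE). The hexose transporter HXT5 was 14.6-fold lower (log2 difference -3.87 ± 0.23 SE). The copper transporter CTR3 was 14.3-fold lower (log2 difference -3.83 ± 0.12 SE). Of 24 general stress genes, 1 rose and 19 fell (1 and 20 adjusted over the list alone, median log2 difference -1.36, adjusted p = 7.7e-13). Of 19 heat shock chaperones, 2 rose and 11 fell (the same adjusted over the list alone, median log2 difference -0.44, adjusted p = 6.0e-04, and adjusted p = 0.11 with an estimated correlation). Of 25 ergosterol synthesis genes, 0 rose and 19 fell (0 and 20 adjusted over the list alone, median log2 difference -0.61, adjusted p = 1.1e-09). Of 33 of sulfur assimilation and methionine synthesis, 7 rose and 19 fell (7 and 22 adjusted over the list alone, median log2 difference -0.44, adjusted p = 5.5e-04, and adjusted p = 0.13 with an estimated correlation). The sulfur list averages opposite directions. Against asparagine it was lower with methionine (median -1.44), higher with leucine (0.37) and not called with phenylalanine. The 1052 higher and 1352 lower calls were 1336 and 1179 with quantile normalization and 1471 and 992 with median centring, the median log2 difference of all tested probe sets being -0.04 as deposited and 0.02 and 0.06 with these scalings. Without the arrays of high ribosomal RNA signal the count of 2404 was 1179, and no array left out on its own moved it by over 1.5 times.

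**Figure D3:**
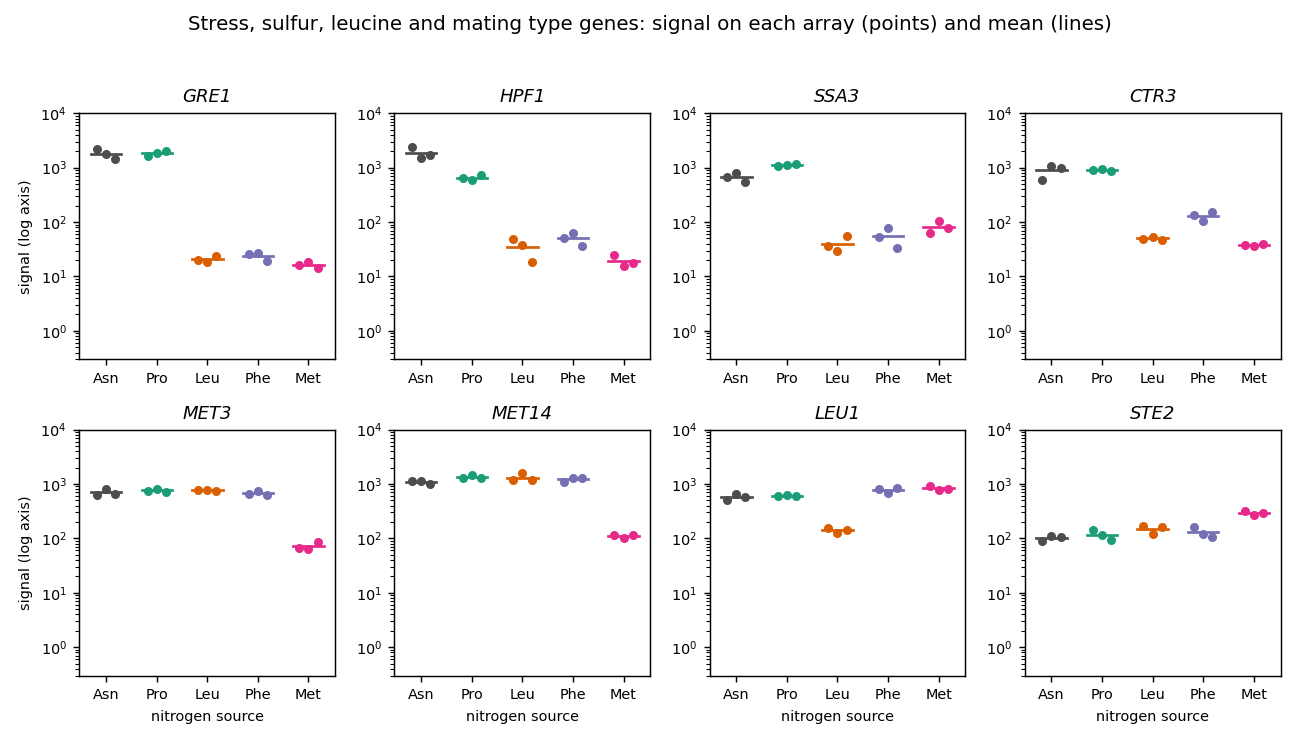
Deposited signal (y axis, log scale) of GRE1, HPF1, SSA3, CTR3, MET3, MET14, LEU1 and STE2 on each of the 15 arrays, as points by nitrogen source (x axis), with the mean of each group. GRE1 averages 1797 with asparagine and 16.3 to 23.8 with leucine, phenylalanine and methionine, LEU1 is lowest with leucine (142), and MET3 (71.7) and MET14 (111) are lowest with methionine.

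Probe sets specific to 1 source were those that differed in 1 direction from each of the other 4 in pairwise limma contrasts. Signals are given as the mean ± SD in that source against the range of the other 4 means. With asparagine 126 probe sets were higher and 107 lower. Lower ones included MEP2 (36.6 ± 7.82 against 823 to 1495), GAP1 (187 ± 34.2 against 1999.6 to 2790.3) and DAL3 (116 ± 8.55 against 596 to 1291), and higher ones the basic amino acid permease ALP1 (273 ± 23.6 against 32.1 to 62.6) and HPF1 (1880 ± 483 against 19.6 to 654). With proline 69 were higher, among them the riboflavin transporter MCH5 (511 ± 73.0 against 49.7 to 88.6), the allantoin permease DAL4 (142 ± 8.40 against 28.2 to 34.9) and the water channel AQY1 (198 ± 17.1 against 16.0 to 84.4). With the same source 51 were lower, among them BAP3 (4.87 ± 1.79 against 290.5 to 437), TAT1 (7.83 ± 0.850 against 136 to 289) and AGP1 (93.3 ± 10.5 against 336 to 1309). With leucine 62 were higher, among them the arginine synthesis enzyme ARG7 (791 ± 21.6 against 217 to 367), the mitochondrial carrier ODC2 (761 ± 36.1 against 199.9 to 367) and HIS5 (451 ± 10.7 against 131 to 241) of histidine synthesis, and 74 lower, among them LEU1 (142 ± 13.6 against 579 to 835), YGP1 (101 ± 4.76 against 848 to 2133) and the membrane heat shock protein HSP30 (54.7 ± 15.5 against 505 to 1531). With phenylalanine 44 were higher, among them ARO80 (41.8 ± 7.45 against 11.2 to 17.2), ARO10 (1996 ± 202 against 37.2 to 1046) and ARO9 (1837 ± 192 against 172 to 1139), and 86 lower, among them threonine aldolase GLY1 (125 ± 29.1 against 255 to 500.2) and the peroxiredoxin AHP1 (448 ± 190.3 against 798 to 1399). With methionine 130 were higher, among them IRC7 (281 ± 18.4 against 15.4 to 43.3), HXT3 (831 ± 67.4 against 74.7 to 299) and the transporter QDR2 (81.7 ± 6.15 against 17.1 to 34.0), and 190 lower, among them MET2 (3.30 ± 1.56 against 321 to 459.9), MMP1 (22.1 ± 4.07 against 307 to 482) and alcohol dehydrogenase ADH2 (421 ± 210.1 against 2672 to 5036).

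The scaling moved these splits too. With quantile normalization and then with median centring, higher and lower probe sets numbered 111 and 168, then 54 and 164, for asparagine, and 86 and 53, then 90 and 45, for proline. For leucine they were 61 and 93, then 37 and 105, for phenylalanine 38 and 43, then 91 and 32, and for methionine 152 and 197, then 155 and 150. The asparagine total of 233 was 136 without asparagine 1, 100 without asparagine 3, 129 without proline 1 and 140 without proline 2, and the proline total of 120 was 68 without asparagine 3, 67 without proline 1 and 78 without proline 2. The phenylalanine total of 130 was 80 without asparagine 2, 85 without proline 1, 75 without leucine 1, 75 without leucine 3, 293 without phenylalanine 2, 74 without phenylalanine 3 and 81 without methionine 3, and the methionine total of 320 was 183 without methionine 2.

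Of the 175 list tests 80 were called by camera with the preset correlation (62 upwards and 18 downwards) and 40 with an estimated one. The lists named next passed in none of the 5 comparisons, and the range of their camera adjusted p-values is given with the counts of single genes in 1 comparison. For the Ehrlich pathway the range was 0.061 to 0.20, and with phenylalanine 10 rose and 10 fell of 31 (12 and 12 adjusted over the list alone). Zinc limitation had 0.055 to 0.74, and with phenylalanine 1 rose and 5 fell of 11 (the same adjusted over the list alone). There the cell wall gene ZPS1 was 3.55-fold lower (from 393 ± 5.09 to 119 ± 53.6). For sulfur source scavenging and sulfonates it was 0.094 to 0.31, and with methionine 0 rose and 4 fell of 7 (the same adjusted over the list alone), with the aryl sulfatase BDS1 at least 4.27-fold lower. Phosphate limitation had 0.10 to 0.45, and with phenylalanine 0 rose and 5 fell of 13 (0 and 6 adjusted over the list alone). There the phosphate transporter PHO84 was 4.77-fold lower (from 59.5 ± 28.5 to 12.0 ± 3.61). Copper uptake had 0.16 to 0.73, and with leucine 0 rose and 2 fell of 7 (1 and 2 adjusted over the list alone), the latter being the transporters CTR3 (17.3-fold) and CTR1 (3.52-fold). For multidrug and weak acid export it was 0.28 to 0.88, and with methionine 6 rose and 6 fell of 21 (8 and 6 adjusted over the list alone), with the transporter QDR2 4.46-fold higher and PDR5 3.07-fold lower. Hexose transport had 0.30 to 0.85, and with methionine 4 rose and 3 fell of 14 (5 and 6 adjusted over the list alone), with HXT4 5.98-fold higher and HXT5 9.75-fold lower. Thiamine synthesis had 0.19 to 0.80, and with methionine 0 rose and 3 fell of 14 (the same adjusted over the list alone), with THI4 4.12-fold lower. For flocculation and invasive growth it was 0.12 to 0.87, and with phenylalanine 2 rose and 2 fell of 9 (the same adjusted over the list alone). The regulator PHD1 was 4.96-fold higher (from 98.4 ± 11.2 to 493 ± 111). Sporulation and meiosis had 0.34 to 0.97, and with methionine 1 rose and 4 fell of 11 (the same adjusted over the list alone). MATalpha identity had 0.22 to 0.85, and with methionine 0 rose and 1 fell of 4 (the same adjusted over the list alone).

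Median, mean and test of an uncalled list differed in sign for sulfur assimilation, multidrug export, glycolysis, cytosolic ribosomal proteins, zinc limitation and MATalpha identity with proline, and for vacuolar proteases and beta oxidation with leucine. The same held for uptake, sulfur assimilation, aromatic synthesis, hexose transport, storage carbohydrate, thiamine, beta oxidation and sporulation with phenylalanine. It also held for multidrug export, hexose transport, cytosolic ribosomal proteins, thiamine, zinc limitation and flocculation with methionine, and for multidrug export and hexose transport in the contrast of 3 sources with 2.

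**Figure D4:**
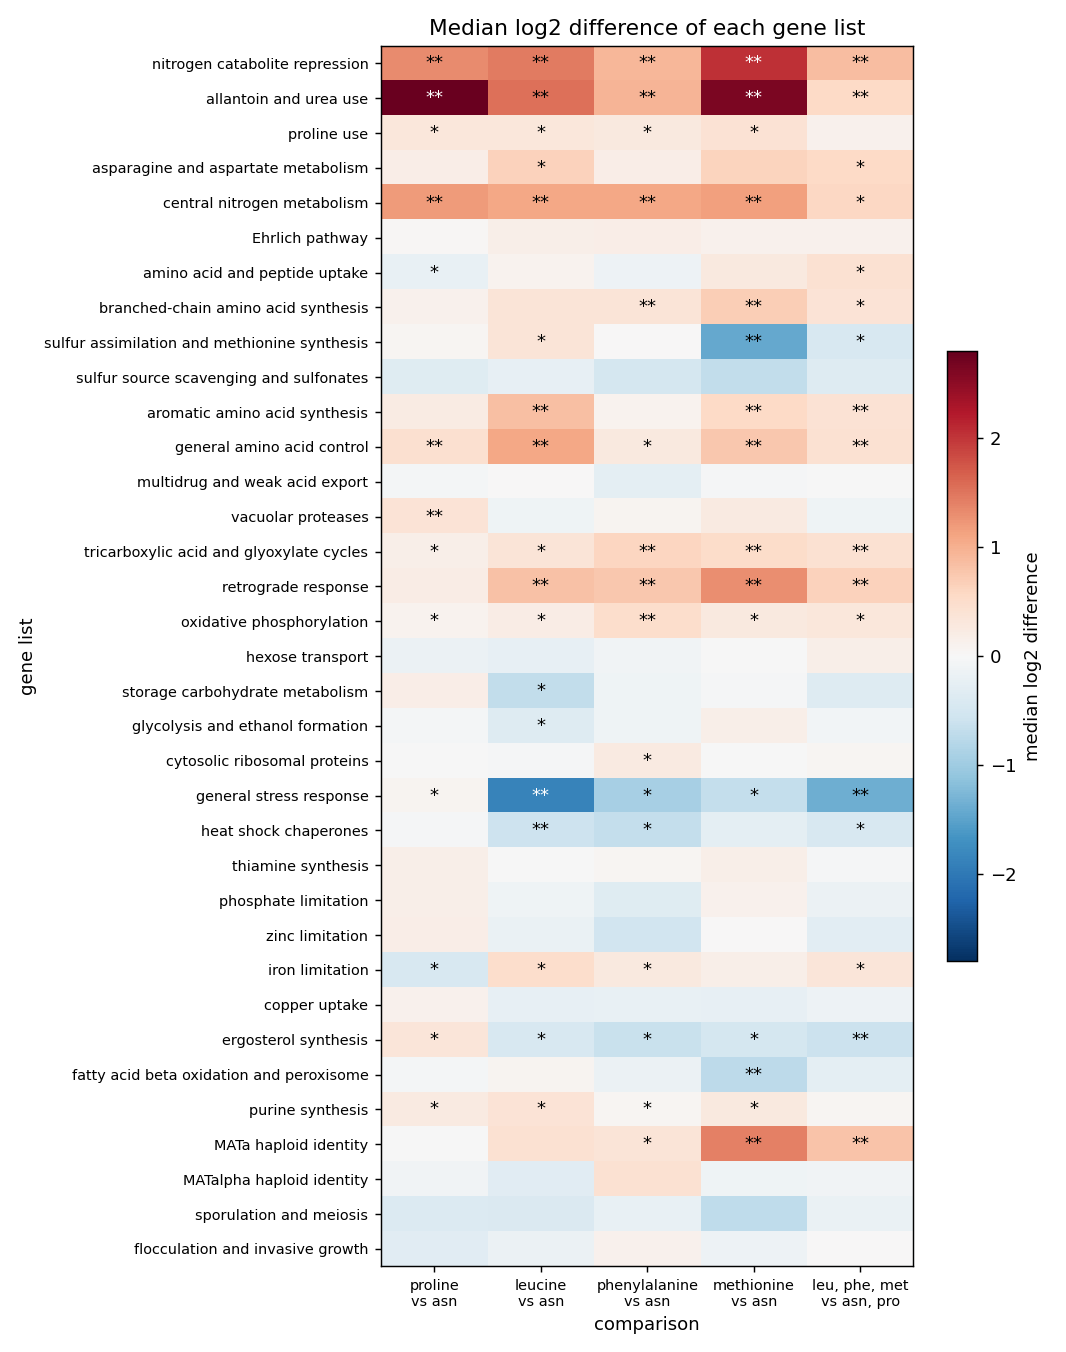
Median log2 difference of each of the 35 gene lists (y axis) in the 5 comparisons (x axis), shown as colour, with 1 star for lists that camera called with the preset correlation and 2 stars for those also called with an estimated one (asn, asparagine, pro, proline, leu, leucine, phe, phenylalanine, met, methionine). The 80 called lists keep the sign of their median under quantile normalization and median centring, while 24 and 23 medians of uncalled lists change sign.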

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

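The covariate tests, the tests of phenylalanine scaling and array codes, and the tests of single methionine arrays and of MATalpha genes were chosen after the results were seen. The signal of the ribosomal RNA control probe sets, which enter no comparison, lay above 33.9, the asparagine mean plus 3 SD, on 5 arrays: 46.6 on proline 2, 98.6 on proline 3, 121.5 on leucine 3, 49.0 on phenylalanine 3 and 171 on methionine 2.

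The first pattern is a set of 299 probe sets from the contrast of 3 sources with 2. Their mean over leucine, phenylalanine and methionine was at least 2-fold below that over asparagine and proline, with a median log2 difference of -1.42. A probe set lower with only 1 of the 3 sources can enter such a set. MET2 averaged 3.30 with methionine but 460 with leucine and 442 with phenylalanine, against 352 with asparagine and 321 with proline. RNA quality or the amount of labelled target could lower such a set, but the actin ratio and the hybridisation control signal overlap between the 3 sources and the other 2, which argues against them as the cause, although for the same reason adjusting for them could hardly move the set (median -1.43 and -1.40, with 299 and 298 still called). The SPT15 ratio is lower with all 3 sources (3.86, 2.99 and 3.57 against 4.45 and 4.35), and with it as covariate the median was -1.39 and 268 of the 299 were still called. This argues only weakly against that trend as the whole cause. The fit takes its slope from differences within groups, and the 299 were chosen for their difference in these same data. Of the 10 ways to set 3 sources against 2, 1, the real one, gave as many 2-fold calls (445), ahead of asparagine, leucine and phenylalanine against proline and methionine (430), a narrow margin. The class of nitrogen source is therefore a candidate explanation, but the set was not split by whether each of the 3 sources was lower. A difference in some other property of the 5 amino acids stays open.

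The second pattern is that more probe sets were lower than higher with phenylalanine, 29.5% of the calls being higher. Quantile normalization and median centring both centre the arrays and so would also remove a real shift. The authors' scaling to 1 trimmed mean and a real excess of lower transcripts therefore cannot be told apart. The share was 51.0% with the first of these scalings and 64.7% with the second, so its direction depends on the scaling. With the phenylalanine array of the usual code alone it was 37.6%, and whether the other codes and the repeat run matter cannot be told apart from this value, since it rests on 1 array. The readings of both tests were changed after their values were seen, because centring moves the share in the first whatever its cause and the bound written for the second (under 40) would have let 1 array decide. Biological causes of the imbalance were not tested.

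The third pattern is the higher signal of MATa genes with methionine (median log2 difference 1.42). Without each methionine array in turn the highest adjusted p of the list was 1.9e-04 (2.8e-06 to 0.013 over all 30 alternatives), which argues against 1 array as the cause. The MATalpha list of 4 genes had a median of -0.11 (0.12 with quantile normalization and 0.04 with median centring), which decides nothing, since cells of that mating type do not express MATa genes and would lower their signal. A pheromone response could raise these genes, and its list of 20 genes, without those of the MATa list and SST2, had a median of 0.053 (0.23 with quantile normalization and 0.20 with median centring), with 6 genes higher and 5 lower, so it cannot be told apart. The bound fixed before that test, a median under 0.1 in a list not called, was met, but members that go both ways make the median the wrong measure, and the readings of this test and of the MATalpha genes were changed after their values were seen; an effect of methionine on these genes also stays open and was not tested.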

How the results depend on the processing

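Named genes past the threshold and the direction of camera in called lists turned in 0 of the alternatives run, but the median of the purine synthesis list with phenylalanine went from 0.06 to -0.03 with phenylalanine 2 as the only array of its group. Of 24692 values of named genes under alternatives 23129 stayed on the same side of the threshold, 1313 lost a call and 250 gained one, and of 5235 of list tests 5096, 73 and 66 did. Where counts moved by over 1.5 times the cause was not tested, except for stricter thresholds and fewer arrays, which can lower counts by construction. The sources are ordered asparagine, proline, leucine, phenylalanine, methionine for specific sets. Quantile normalization gave 81 specific to phenylalanine (130 as deposited), and array weights 2095 for proline (992) and 443, 241 and 206 specific to the first 3 sources (233, 120 and 136). At least 2-fold were 1824 of 3892 among the 5 sources, 383 for proline, 599 for leucine, 587 for phenylalanine, 1117 for methionine, 445 for 3 sources against 2, and 59, 49, 41, 14 and 116 specific ones. An adjusted p under 0.01 left 2295, 321, 992, 912, 1830, 1543 and 78, 57, 71, 40 and 135, and an estimated correlation 40 of 80 list tests. With only the 2 groups fitted phenylalanine had 840 (1910), and with 1 phenylalanine array 921, and 76 specific. Of the alternatives chosen after seeing the data, the actin ratio gave 330 for proline, 1854 for methionine and 110, 74, 58 and 193 specific to asparagine, proline, phenylalanine and methionine, the SPT15 ratio 822 for phenylalanine and 144 specific to asparagine, and the hybridisation controls 476 for proline and 61, 44 and 211 specific to proline, phenylalanine and methionine. Without the 5 arrays of high ribosomal RNA signal, which leaves 1 for proline, there were 1902 among the 5 sources, 173 for proline, 895 for phenylalanine, 1179 for 3 against 2, and 44, 35, 60, 13 and 102 specific. Each array left out in turn gave 3253 to 4443 among the 5 sources, 366 to 1251 for proline, 1146 to 1773 for leucine, 1174 to 2398 for phenylalanine, 2227 to 3171 for methionine, 2049 to 2679 for 3 against 2, 100 to 309, 67 to 144, 98 to 159, 74 to 293 and 183 to 361 specific, and 78 to 90 list tests. Same-numbered arrays were treated as unpaired, and whether they belong together stays open: 30 pairs had r of -0.25 to 0.40 (median 0.015), 10 of them over 0.1, and 8 of 15 arrays correlated best with their own number. With that number as a replicate block the counts were 3840, 963, 1514, 1861, 2862 and 2372, 225, 113, 141, 116 and 323 specific, and 80 list tests, and ARO3 with phenylalanine was not called (0.055, in a range of 0.011 to 0.54 over 33 alternatives). Signal over background limits dim genes: without detection flags, levels at or below 9.9 have only a bound.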

Other observations

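The gene lists and genes of the next 2 paragraphs were chosen after the data were examined, the list of pheromone-responsive genes before its own values were seen, and the regroupings after them were planned. Seripauperins and other cell wall mannoproteins known from anaerobic growth moved with the nitrogen source, although the cultures were aerobic. Of 16 measured genes, 10 of them on probe sets with shared sequence and so uncertain, 11 rose with proline (median log2 difference 0.99, camera adjusted p = 2.7e-09), while 14 fell with leucine (-1.43, 3.1e-10), 13 with phenylalanine (-1.28, 8.2e-07) and 14 with methionine (-1.18, 2.0e-06). In the contrast of 3 sources with 2, 14 fell (-1.74, 4.3e-12). With an estimated correlation the adjusted p was 0.29, 0.29, 0.34, 0.34 and 0.29 in that order, so no call held, and no median changed sign under quantile normalization or median centring. PAU7 averaged 251 ± 61.7 with asparagine, 609.6 ± 68.7 with proline and 56.5 ± 3.30 with leucine, and TIR3 501 ± 71.2 with asparagine and 84.5 ± 25.4 with methionine.

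Among other groups, 11 of 25 ribosome biogenesis genes fell with phenylalanine (adjusted p = 0.040, and 0.74 with an estimated correlation), but 5 with quantile normalization and 2 with median centring, and 3 fell with proline (0.023, and 0.66). Of 31 proteasome genes, 11 fell with phenylalanine (0.040, and 0.66), 11 with quantile normalization and 2 with median centring, and 11 fell in the contrast of 3 sources with 2 (0.013, and 0.47), 14 with quantile normalization and 5 with median centring. Of 4 measured histone genes 2 rose with phenylalanine (0.036, and 0.34). Of 4 measured mitochondrially encoded genes 2 rose with methionine (median log2 difference 0.90, adjusted p = 0.25), where COX1 had a wide spread (373 ± 276). Of 20 pheromone-responsive genes 6 rose and 5 fell with methionine, and of the former FAR1, an inhibitor of the cell cycle, was at 158 ± 19.3 against 59.9 ± 1.78 with asparagine, and the kinase FUS3 at 243 ± 31.6 against 123 ± 31.3.

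Other groupings were fitted. Of 100 groupings of the 15 arrays, 99 of them drawn at random, 1, the real one, gave as many calls in each of 7 counts. For differences among the 5 sources this argues against chance at that number of draws. Random groupings mix sources within a group, which raises the spread, so low counts follow from any effect of the sources. They therefore cannot test the contrast of 3 sources with 2 or a set specific to 1 source. The real and the highest other count were 3892 and 511 for differences among the 5 sources, 2404 and 42 for the contrast of 3 sources with 2, and, for probe sets specific to 1 source, 233 and 0 for asparagine, 120 and 13 for proline, 136 and 100 for leucine, 130 and 0 for phenylalanine and 320 and 121 for methionine. With each source kept whole, the other ways to set 3 sources against 2 called 657 to 2266 probe sets, against 2404. For a comparison of 3 arrays with 3, the 10 splits are too few for a share under 0.05, the real split being 1 of 10 in each case. The real and the highest other count were 992 and 3 for proline, 1560 and 0 for leucine, 1910 and 0 for phenylalanine and 2876 and 0 for methionine.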
